A study of Homo sapiens with 2 samples.

How the data were processed

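Gene expression was measured in normal human epidermal keratinocytes, the main cell type of the outer skin, on Affymetrix Human Genome HU133A 2.0 arrays, which read each transcript with sets of short probes. Per the labels' protocols, confluent cultures in 35 mm dishes were wounded with a cross-shaped gap. The treated cultures then stood for 1 h in an induced electromagnetic field (EMF). The field had 2080 cycles per second, 20 mV/cm and a duty cycle of 90%. The control cultures stood in the same hood without the field for 1 h. For both conditions the temperature in that hour was 31 °C, give or take 2 °C. Cells were otherwise kept at 37 °C. Per the labels' protocols, 3 cultures per condition were combined for RNA extraction, and 1 array was hybridised per condition, so the 2 arrays carry no replicate and no p-value is given for any gene or list. The number of arrays limits the precision of every value.

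The deposited values are signal intensities per probe set on a linear scale, made with MAS5 per the submitters' processing notes. The version of MAS5 is not given in the sources used here, and detection calls and scanner files were not used here. The values were checked for scale: the mean of the deposited intensity values after leaving out the lowest and highest 2% of probe sets was 500.1 on both arrays, which fits a scaling of each array to 500 by the authors. Signals were used as deposited, with no further normalization in the main setting.

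Of 22277 probe sets, 62 were array controls, 19070 had 1 gene symbol in the platform annotation, 1043 had several and 2102 were not listed or had no symbol there. Symbols were updated through the gene ID to a gene table of assembly GRCh38.p14, which held 19058 of the 19070. The sources used here name no genome build for the array, so no coordinates are given. XIST and Y-linked genes were left out. The probe sets with 1 symbol gave 11939 genes, each represented by its probe set with the highest mean signal.

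Signals near background have no reliable ratio. A floor was therefore set at the 90th percentile of the signals, over both arrays, of 145 probe sets of genes restricted to tissues far from skin, such as olfactory receptors and genes of liver, pancreas, eye and testis (102 of the 120 genes on that list had a probe set). The floor was 85.88. For a gene above it on both arrays, the log2 difference EMF minus untreated was taken. For a gene above it on 1 array only, a bound against the floor was given as "at least N-fold". For a gene below it on both arrays no fold was given. A size rule of 2-fold marked genes, and the words higher and lower describe these 2 arrays.

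Gene lists were described by the median log2 difference of the members above the floor on both arrays, set against the medians of 10000 random lists of the same size matched on 10 classes (deciles) of mean log2 signal. A list was said to stand apart when its percentile was under 2.5 or over 97.5. Lists with fewer than 5 measured members were given no percentile. The percentile describes these 2 arrays and is no test between the conditions. The 27 gene lists covered immediate early genes, heat shock and cytosolic chaperones, DNA replication, mitosis, cyclin-dependent kinases, HOX genes, integrins and laminins, matrix proteases, actin regulators, basal and differentiation markers, wound-activated genes, EGF and TGF-beta signalling, cytokines and NF-kB targets, interferon-stimulated genes, ER stress, p53, NRF2 targets, glycolysis and hypoxia, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, calcium channels, calmodulin and NFAT, ion transport and cell junctions. A further 5 lists held markers of fibroblasts, melanocytes, immune cells, endothelial cells, and Merkel and nerve cells.

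The genes named were chosen by a rule. It took the 12 genes with the largest positive and the 12 with the largest negative log2 difference whose other probe sets above the floor on both arrays, if any, all differed in the same direction. It took the 3 genes with the largest bound in each direction by the same condition. In each list it took up to 4 members at least 2-fold different, or otherwise the 2 measured members with the largest absolute difference. It also took HOXC8 and CDK12 whatever their values, because the study's paper is known to discuss them, CDK12 under the name CRK7. The study picked that pair from these same samples, so they are no independent evidence, and they are also why the HOX and cyclin-dependent kinase lists were included. The lists, the floor, the size rule, the naming rule and the alternatives were fixed before the data were examined.

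The spread without replicates was described by the SD of the log2 differences of the array's 100 normalization-control probe sets, by the SD over genes in each decile of signal, and by the difference between probe sets of the same gene. The last is measured within 1 pair of RNA pools, so it covers noise of the probe sets and not the variation between cultures. The procedure was tested on simulated data with the noise of these arrays at each signal level. In that test of the EMF comparison, run on 7197 genes, the 2-fold rule recovered 88% of 50 genes given a log2 change of 1.25 and 98% of 50 given 1.5. It recovered 100% of the 50 genes given a change of 2 and of the 50 given 3. The changed genes were drawn only from genes well above the floor. Recovery of dim genes, where the 2-fold calls of these arrays lie, was therefore not tested. Of 6997 genes given no such change, 10 passed it. A list of 29 genes lowered by 0.15 lay at percentile 1.28, and 0 of 20 random lists stood apart. These simulations take their noise from the observed differences between the 2 arrays, any real change included, and cannot show how cultures vary.

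Alternatives tried were 4 other scalings (equal medians, quantile normalization, centring on the normalization controls, loess with a span of 0.4), other floors (75th percentile of the background list, median of all probe sets, none), the floor added to both signals before log2, the mean of a gene's probe sets, leaving out probe sets whose IDs mark shared probes (ending in _x_at or _s_at), size rules of 1.5-fold and 3-fold, list members at their bound, and random lists without matching. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.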

Results

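The series holds 2 arrays of scratch-wounded human keratinocytes, 1 from cultures left untreated for 1 h and 1 from cultures exposed for 1 h to a non-invasive electromagnetic field (EMF). The question named by the study's title is how such a field affects keratinocyte migration and proliferation, and the arrays compare transcript levels directly after the exposure. Each array carries RNA combined from 3 cultures. There are no replicate arrays, so no difference below has a replicate check. The MAS5 signals had a median of 133.7 on the untreated and 143.2 on the EMF array and reached 27090.3 and 30022.8. With the array controls left out, signals above the background floor of 85.88 made up 56.9% of probe sets (12640) on the untreated and 58.81% (13065) on the EMF array.

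Both pools had the profile of cultured epidermal keratinocytes. The basal keratins KRT5 and KRT14 had signals of 22021.8 and 23628.5 in the untreated pool and 24043.6 and 26144.0 in the EMF pool, and the epidermal calcium-binding protein S100A2 had the brightest probe set of the gene comparison on each array. KRT16, a keratin of activated and wounded epidermis, stood at 14190.1 and 13863.2. The melanocyte genes MLANA, PMEL, TYR and TYRP1, the leukocyte genes PTPRC and CD74 and the endothelial genes PECAM1, VWF and CDH5 were below the floor on both arrays. Of the marker lists, 1 of 12 melanocyte genes (ERBB3, log2 difference -0.02), 0 of 16 immune cell genes, 1 of 11 endothelial genes (ROBO4, 0.40) and 2 of 9 Merkel and nerve cell genes (NEFL, -0.23, and NEFM, 0.15) were above the floor on both arrays. Among fibroblast markers 7 of 20 were above it, 6 of them higher after EMF, with a median log2 difference of 0.051 (percentile 47.2), negative under quantile normalization and loess. VIM, an intermediate filament gene of mesenchymal cells that cultured keratinocytes can also express, read 95.03 untreated and 183 after EMF (log2 difference 0.95), and SPARC, the lower one, differed by -0.33, with another SPARC set at 58.0 and 92.5. COL1A2 crossed the floor upward, at 8.89 and 101, at least 1.17-fold higher. The marker genes given here by signal, other than those picked by the naming rule, were chosen after their values were seen.

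RNA quality and hybridization controls read as follows. The ratio of 3' to 5' signal was 0.819 untreated and 0.827 after EMF for GAPDH and 1.08 and 1.03 for ACTB. The 18 hybridization spike-in probe sets had a median log2 difference of 0.056. The 27 Bacillus control probe sets, all below the floor, had a median of 0.80, with 19 higher after EMF. The 100 normalization-control probe sets had a mean log2 difference of -0.024 with an SD of 0.12 across probe sets, and the largest absolute difference among them was 0.46.

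Few genes differed by 2-fold between the EMF and the untreated array. Of 7200 genes above the floor on both arrays, 6966 (96.75%) lay within 1.5-fold, 10 were at least 2-fold higher after EMF and 4 at least 2-fold lower. The split of 10 against 4 became 7 against 7 with loess centring and 8 against 6 with quantile normalization, and under both TTC12, FRMD8 and CENPA no longer passed the rule. The counts followed the floor: 62 higher and 16 lower with the floor at the 75th percentile of the background list, 1 and 0 with it at the median of all probe sets, and 1 and 1 with the floor added to both signals. In data simulated for this comparison on 7197 genes, 10 of 6997 unchanged genes passed the same rule. The simulated spread was taken from the observed differences of these 2 arrays, any real change included. A count of like size is therefore built in and cannot separate noise from an effect. The largest differences of genes above the floor on both arrays were 2.795-fold higher and 2.95-fold lower. At 1.5-fold, 150 genes were higher and 84 lower.

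Among genes above the floor on both arrays, those with the highest relative signal after EMF were UBQLN4, a ubiquilin that shuttles proteins to the proteasome (118 untreated, 329.5 after EMF, log2 difference 1.48), and APOE, a lipid transport protein (109 and 287, 1.40). The non-coding DLEU2 differed by 1.33, IDI2-AS1 by 1.16 and the annexin pseudogene ANXA2P3 by 1.14. ARHGAP44 differed by 1.12, the HSP40 family member DNAJA4 by 1.11, TTC12 by 1.06, FRMD8 by 1.03 and CENPA, the centromeric histone H3 variant, by 1.00. NPPA, the precursor of atrial natriuretic peptide, and EPN3, an epsin of endocytosis, came next at 0.99 and 0.98, just under the size rule. For APOE and ARHGAP44 another probe set crossed the floor in the other direction: the APOE set read 97.3 untreated and 39.54 after EMF, and the ARHGAP44 set read 112 and 66.1. The remaining APOE set read 77.1 and 90.4.

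On the other side, KRI1, a nucleolar protein of ribosome assembly, read 328 untreated and 111 after EMF (log2 difference -1.56). BCL7C, a SWI/SNF chromatin remodelling subunit, read 302 and 109 (-1.47), and the membrane protein gene TMEM53 differed by -1.03. The chemokine CXCL2 read 1461 and 760.4 (-0.94) and the leukocyte adhesion molecule ICAM1 read 163 and 85.96 (-0.92). CINP differed by -0.94, TFPT by -0.93, CYP20A1 by -0.89, IMPACT by -0.89, PRKAA1, a catalytic subunit of AMP-activated kinase, by -0.86, the basement membrane proteoglycan HSPG2 by -0.84 and the dynein regulator NDE1 by -0.81. The fourth gene at least 2-fold lower was ARNT, the partner of the hypoxia-inducible factors, at -1.27. It falls outside the naming rule and was chosen after its values were seen: its other 2 probe sets above the floor differed by 0.59 and -0.13.

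All 14 genes at least 2-fold different lay in the lowest 3 of 10 signal deciles, where the spread was widest. The SD of the log2 difference across genes was 0.35 in the dimmest decile, 0.36 in the next and 0.13 in the brightest. Of the 14, ARNT alone had another probe set above the floor on both arrays, and 5 rested on probe sets whose IDs, ending in _x_at, mark probes that can match other transcripts, namely UBQLN4, APOE, DLEU2, CENPA and ARNT.

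**Figure D1:**
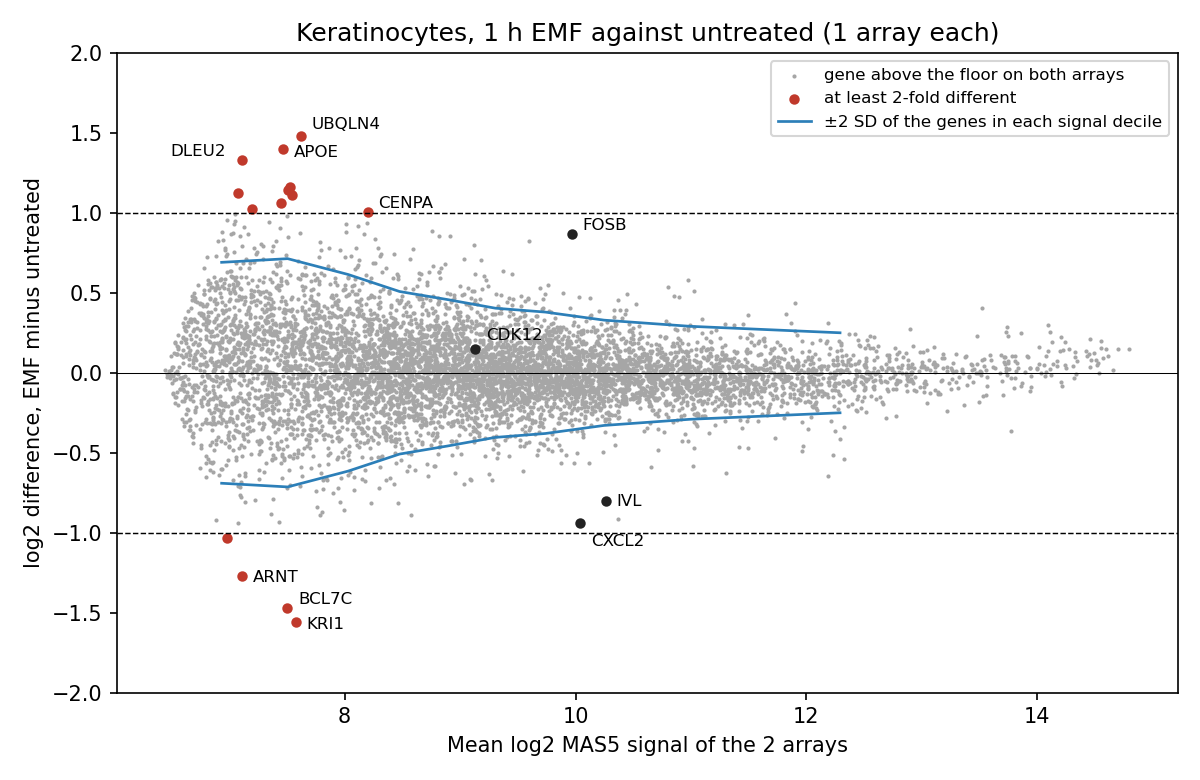
Each point is 1 of the 7200 genes above the floor on both arrays, with its mean log2 MAS5 signal on the x axis and its log2 difference, EMF minus untreated, on the y axis; dashed lines mark 2-fold, red points the 14 genes past it, and blue lines 2 SDs of the genes in each signal decile. The red points lie at low signal, while CXCL2 (-0.94), IVL (-0.80) and FOSB (0.87), in black, lie outside the blue lines at higher signal and CDK12 (0.15) lies inside.

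Some genes crossed the floor. There were 448 genes above it on the EMF array only and 210 on the untreated array only. A bound of at least 2-fold was reached by 6 of the former and 3 of the latter. Genes below the floor on both arrays also read higher on the EMF array, with a median log2 difference of 0.32. The larger number on the EMF array is therefore not read as more genes switched on. The largest bounds were at least 2.99-fold higher for the RNA helicase DDX31, at least 2.35-fold higher for RCBTB2 and at least 2.14-fold higher for TMPRSS6, the serine protease matriptase-2. In the other direction ADAM8, a membrane metalloprotease, was at least 2.35-fold lower, the signalling adaptor GAB2 at least 2.18-fold lower and TRABD at least 2.09-fold lower.

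HOXC8, a homeobox transcription factor, read 12.7 untreated and 80.6 after EMF, below the floor on both arrays, so no fold is given. CDK12, a kinase of RNA polymerase II, read 532 and 591 in its brighter probe set (log2 difference 0.15). Its second probe set read 51.8 and 109, at least 1.27-fold higher. Of the HOX list, 5 of 24 genes were above the floor on both arrays, with a median of 0.15 (percentile 78.2), led by HOXC13 (0.58) and HOXC11 (0.28). The list of cyclin-dependent kinases, G1 cyclins and inhibitors had 11 of 28 members higher and a median of -0.030 (percentile 21.2), with CCNT1 at 0.59 and CDK19 at 0.49. Both genes were picked by the study from these samples, and both lists follow from that choice, so they are not independent evidence.

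Of 28 lists given a percentile, 3 stood apart from random lists of like signal, where 1.4 would by chance. The 1.4 takes list members to vary independently, as randomly drawn genes do. Members of a list can move together and some lists share genes, so 1.4 may be too low. Heat shock and cytosolic chaperone genes were lower after EMF, with 21 of 29 members below 0 and a median log2 difference of -0.092 (percentile 0.33). HSPE1, the mitochondrial HSP10, differed by -0.46 (3215 untreated, 2335 after EMF) and the HSP70 and HSP90 co-chaperone STIP1 by -0.42. Interferon-stimulated genes were higher, with 25 of 36 members above 0 and a median of 0.081 (percentile 98.7), led by IFI6 (0.47) and the ISG15 ligase HERC5 (0.35). Cytosolic ribosomal protein genes had 36 of 52 members above 0 and a median of 0.029 (percentile 97.8), which turned to -0.050 under quantile normalization and was 0.00049 (percentile 42.3) with loess, with RPLP2 at 0.49 and RPL34 at -0.37. None of these 3 lists had a member at least 1.5-fold different. The heat shock list lay at percentile 39.2 (median -0.029) without probe sets of shared probes and at 7.53 (-0.053) with the mean of a gene's probe sets.

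**Figure D2:**
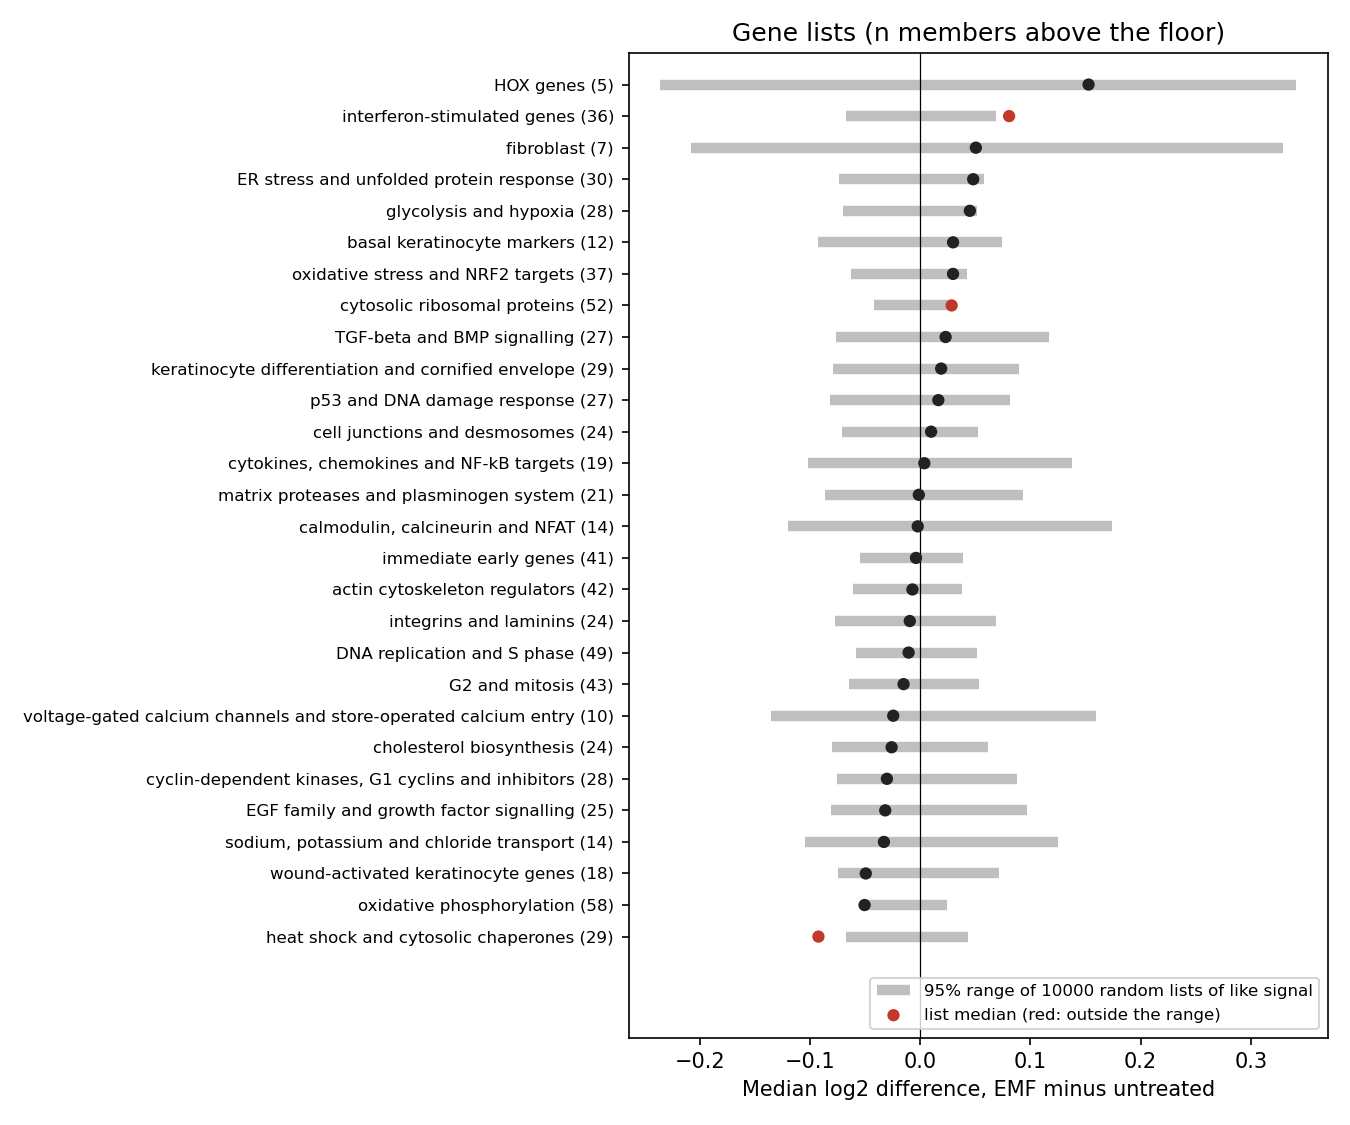
Each dot is the median log2 difference, EMF minus untreated, of the members of 1 of 28 lists, with the number of measured members in brackets, and each grey bar is the range holding 95% of 10000 random lists of like signal. The red dots outside their bars are heat shock and cytosolic chaperones (-0.092), interferon-stimulated genes (0.081) and cytosolic ribosomal proteins (0.029, which is -0.050 under quantile normalization).

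Mitochondrial and metabolic lists lay inside their random ranges, oxidative phosphorylation only narrowly. Its 58 measured genes had 38 members lower and a median of -0.050 (percentile 2.81), and the list stood apart as lower in 5 of 12 alternative settings, with the complex I subunits NDUFB6 at -0.43 and NDUFS7 at 0.37. Glycolysis and hypoxia genes had a median of 0.045 (percentile 96.0), with ALDOC at 0.47 and P4HA1 at -0.38. The cholesterol synthesis list, which also holds fatty acid genes, had a median of -0.026 (percentile 30.8). The fatty acid elongase ELOVL6 was at -0.58 and MSMO1 at -0.29.

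Stress and immediate early gene lists, other than heat shock, stayed inside their random ranges, with single members further from 0. FOSB, an AP-1 subunit, read 742 untreated and 1353 after EMF (log2 difference 0.87), and the orphan nuclear receptor NR4A1 differed by -0.64 in its main probe set, while the 41 measured immediate early genes split into 20 higher and 21 lower with a median of -0.0038 (percentile 46.7). Another NR4A1 probe set read 28.5 untreated and 137 after EMF, the other direction. In the ER stress list, 20 of 30 members were higher, with a median of 0.048 (percentile 95.6), and it stood apart under quantile normalization (0.079, percentile 99.4). Its sensors went opposite ways, ERN1 (IRE1) at 0.80 and ATF6 at -0.66. The p53 and DNA damage list had a median of 0.017 (percentile 66.5), with PCBP4 at 0.60 and the phosphatase PPM1D at -0.53. Over the alternative settings its median went as low as -0.11 and its percentile as low as 3.02. NRF2 and oxidative stress targets had a median of 0.030 (percentile 93.5), with AKR1C2 at -0.44 and GSTM1 at 0.36. Cytokines, chemokines and NF-kB targets, which hold CXCL2 and ICAM1, had 10 of 19 members higher and a median of 0.0038 (percentile 43.1). Of the 19, 3 were at least 1.5-fold lower and 0 at least 1.5-fold higher. Among all 7200 measured genes, 84 were at least 1.5-fold lower and 150 higher.

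The lists of keratinocyte differentiation and wounding had medians inside their random ranges, with members on both sides of 0. Involucrin (IVL), a precursor of the cornified envelope, read 1622 untreated and 928 after EMF (log2 difference -0.80), and TGM1, the transglutaminase that crosslinks it, read 310.2 and 184 (-0.75). The rest of the differentiation list went both ways, so that 15 of 29 members were higher and the median was 0.019 (percentile 64.3). Basal markers had a median of 0.030 (percentile 82.8; 0.10 and percentile 99.2 with the mean of a gene's probe sets), with JAG2 at 0.23 and IGFBP3 at -0.20. Wound-activated genes had 14 of 18 members lower and a median of -0.049 (percentile 9.53), with the matrix protein tenascin-C (TNC) at -0.54 and SERPINB4 at -0.36.

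Lists tied to proliferation and migration, the question of the study, also lay inside their random ranges. DNA replication and S phase genes had a median of -0.011 (percentile 40.3), with cyclin E2 (CCNE2) at 0.49 and thymidine kinase (TK1) at -0.39. Mitosis genes had 21 of 43 members higher and a median of -0.015 (percentile 40.9). CENPA was the only list member at least 2-fold different among 757 measured genes of the 27 gene lists, of which 18 differed by at least 1.5-fold. It was at 0.99 with equal medians, 0.98 with quantile normalization and 0.97 with loess, under the rule in each. Integrins and laminins had a median of -0.0094 (percentile 42.3), with TNC at -0.54 and the integrin activator FERMT2 at 0.44. Matrix proteases had a median of -0.0012 (percentile 45.8), with TIMP2 at -0.62 and the gelatinase MMP9 at 0.48. Actin regulators had a median of -0.0070 (percentile 51.9), with LIMK2 at 0.39 and RAC2 at -0.39. Cell junction genes had a median of 0.0099 (percentile 69.0), with occludin (OCLN) at 0.55 and CLDN7 at -0.39. In the list of EGF family and growth factor signalling, the FGF receptor FGFR2 was at -0.63 and the ligand HBEGF at 0.51, and the list median was -0.032 (percentile 21.0). Other probe sets of these genes above the floor on both arrays did not follow, at 0.23 and 0.12 for FGFR2 and -0.02 for HBEGF. An FGFR2 set above it on the untreated array only read 162 and 82.8, the direction of the main set. Another, above it on the EMF array only, read 40.7 and 92.9, the other direction. TGF-beta and BMP signalling had a median of 0.023 (percentile 60.3), with SKIL at -0.52 and SMAD7 at 0.45.

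Lists of calcium signalling and ion transport lay inside their random ranges as well. Calcium channels and store-operated entry had 10 of 35 genes above the floor on both arrays and a median of -0.024 (percentile 31.5), with PLCD1 at -0.46 and the calcium sensor STIM1 at 0.31. Over the alternative settings the median of this list ran from -0.070 to 0.29 and its percentile from 19.8 to 88.4. Calmodulin, calcineurin and NFAT genes had a median of -0.0022 (percentile 38.9), with CREM at 0.39 and ATF2 at -0.38. Sodium, potassium and chloride transport genes had a median of -0.033 (percentile 23.3), with CLCN6 at -0.64 and SLC12A7 at -0.36. The sign of the median differed under another scaling for 14 of the 28 lists. For 7 of them it did so only under scalings that shift all genes by the same amount and leave the percentile as it is.

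A second probe set of the same gene gives a check within the same RNA. Over 2442 genes with 2 or more probe sets above the floor, the log2 differences of the brighter and the second probe set correlated across genes with a Pearson r of 0.080, genes not being independent replicates. The SD of the difference between probe sets of a gene was 0.33, against an SD of 0.21 for the brighter set itself. The shared part, the square root of their covariance, was 0.067. Over the 387 genes with probe sets of neither shared kind, r was 0.11. Of the 87 genes named by the rule, 16 had another probe set above the floor on both arrays, and in 8 of these such a set differed in the other direction (FGFR2, HBEGF, CCNE2, LIMK2, IGFBP3, AKR1C2, ATF2 and NEFL). A further probe set above the floor on 1 array was present for 9 genes and went the other way in 5 (APOE, ARHGAP44, NR4A1, SPARC and FGFR2).

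**Figure D3:**
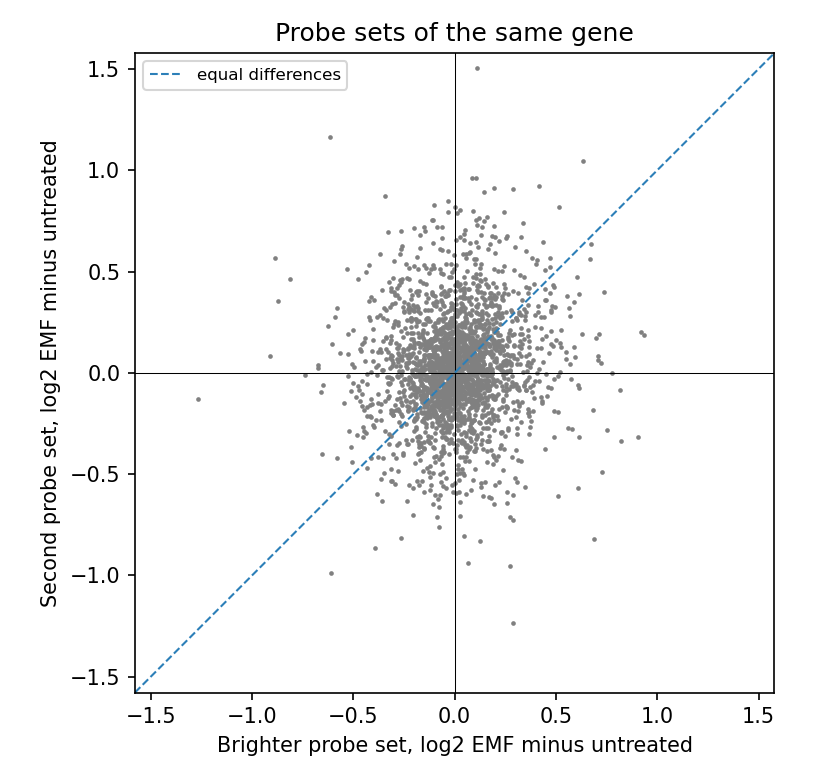
Each point is 1 of 2442 genes, with the log2 difference, EMF minus untreated, of its brighter probe set on the x axis and of its second probe set on the y axis, and the dashed line marks equal values. The points form a cloud around 0 that does not follow the line (Pearson r 0.080 across genes).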

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

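The tests on dim probe sets given here were chosen after the result was seen. The Bacillus control probe sets drew attention because they lie outside the gene comparison and match no human RNA, yet were higher on the EMF array: the median log2 difference of 27 such sets was 0.7964, with 19 higher. Their signals reached at most 69.48, below the floor, and single sets ranged from -3.31 to 4.39. The median signal of these sets was 7.15 untreated and 7.97 after EMF, far below the floor, where ratios are not reliable. Genes below the floor on both arrays were also higher on the EMF array, with a median log2 difference of 0.32, while genes above it had a median of 0.0039. A candidate explanation is array background or scaling, under which probe sets of genes silent in skin would be higher as well. The median of 145 probe sets of genes of distant tissues was 0.442, with 97 higher, but the floor was set so that most of them lie below it, so this largely restates the observation on dim genes. The median was 0.086 in the dimmest decile of measured genes and -0.0018 in the brightest, and whether any part of it comes from the field stays open with 1 array per condition.

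Of 1380 probe sets above the floor on both arrays that lack a single gene name, and so were in no gene comparison, 1 was at least 2-fold higher on the EMF array and 3 were at least 2-fold lower.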

How the results depend on the processing

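The alternatives given in this part were all planned, and none of them was chosen after the result was seen. The 2-fold counts, 10 higher and 4 lower, depended most on the floor: 62 and 16 with the 75th percentile of the background list, 1 and 0 with the median of all probe sets, 1275 and 620 with no floor, and 1 and 1 with the floor added to both signals, since that shrinks dim ratios by construction. Without probe sets of shared probes 6 were higher, and loess centring gave 7 lower. At 1.5-fold there were 150 and 84, and at 3-fold 0 and 0. Of 28 lists, 3 stood apart, against 5 with quantile normalization and 1 with unmatched random lists. The ribosomal protein median turned from 0.029 to -0.050 under quantile normalization; the cause was not tested. The heat shock list stood apart in 10 of 12 settings, the interferon list in 11 (percentile 97.15 to 99.26 over the 12) and the ribosomal list in 7 as higher and in 1, quantile normalization, as lower. Centring on equal medians or on the normalization controls leaves percentiles as they are, so these settings could not change a call. Heat shock was lost where other probe sets were read: with the mean of a gene's probe sets (percentile 7.53) and without those of shared probes (39.2). Oxidative phosphorylation, inside its range in the main setting, stood apart in 5, and the ER stress and basal lists in 1 each. Of the list medians under the alternatives, 309 moved by less than 1 SD of random lists, 22 by more, and 1, the ribosomal median, turned in a list that stands apart. Medians near 0 of lists inside their ranges also changed sign and are counted by the size of the move. Of named-gene values, 688 moved by less than the SD of the normalization controls and 52 by more. No named gene at least 2-fold different changed sign where it was measured. None of those genes had another probe set above the floor on both arrays, so averaging or leaving out probe sets could not turn a sign. Many of the values counted here could not move. Another floor leaves the value of a measured gene as it is, and the constant shifts (equal medians, normalization controls) are smaller than that SD. Unmatched random lists likewise leave every list median as it is. No paired analysis was possible because there is 1 array per condition. Signal near background limits the dim genes, where the 2-fold calls lie.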

Other observations

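The tests on genes at least 1.5-fold or 2-fold different and on IVL and TGM1 were chosen after the result was seen, as were all genes and families in the next 2 paragraphs. The tests of the heat shock and interferon lists were written before.

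Genes were also measured against genes of like brightness. At 4 or more times the SD of their signal decile lay 15 genes, 11 lower and 4 higher after EMF. Among the lower ones were CXCL2 (-5.73 SDs), the stress-induced mTORC1 inhibitor DDIT4 (5842 untreated, 3737 after EMF, log2 difference -0.64), the mRNA decay factor ZFP36 (-0.54), the AP-1 subunit FOS (5740 and 4020.1, -0.51) and the arginyl-tRNA synthetase RARS1 (-0.63). FOSB, the amino acid transporter subunit SLC3A2 (1644 and 2464, 0.58), EPOR (0.82) and UBQLN4 were the higher ones. The 2-fold genes KRI1 (-4.37 SDs) and BCL7C (-4.12 SDs), with IVL, SLC25A16, GALNT2 and LSM7, completed the 15. FOS and FOSB, both immediate early genes, thus went opposite ways. Of the 15, 2 had another probe set above the floor, and in 0 of them did it share the direction. CXCL2, SLC25A16 and UBQLN4 rested on probe sets ending in _x_at, and DDIT4, GALNT2, LSM7 and SLC3A2 on sets ending in _s_at. Both endings mark shared probes. EPOR rested on a set ending in _f_at and is not taken as specific to 1 gene either.

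Across 17 gene families grouped by symbol, 0 stood apart in their representative probe sets. Closest were proteasome subunits, with 24 of 33 members lower and a median of -0.060 (percentile 3.97), mitochondrial ribosomal proteins, with 36 of 48 lower and a median of -0.061 (percentile 3.79), and splicing factors, with 31 of 46 lower and a median of -0.052 (percentile 4.10). The second probe sets of 12 proteasome genes had a median of -0.11 (percentile 2.18). Those of 29 splicing factors had a median of 0.036 (percentile 87.6) and those of 7 mitochondrial ribosomal proteins 0.024 (percentile 44.8), the other side of 0 from their main sets. Among second probe sets of the gene lists, NRF2 targets lay at percentile 99.6 (median 0.16, 15 genes) and wound-activated genes at 2.22 (median -0.15, 7 genes). Neither list stood apart in its main probe sets. Both were picked from all gene lists with at least 5 second sets, where some would lie this far out by chance. Second sets of 20 ribosomal protein genes had a median of 0.078 (percentile 97.4), and those of 15 oxidative phosphorylation genes 0.0047 (percentile 53.4).

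The genes at least 1.5-fold different may owe much of their difference to probe set noise. If so, a gene's other probe sets would not follow: their mean log2 difference, taken in the direction of the main set, was 0.01546 (standard error 0.058 over 45 genes, 21 in the same direction), against 0.72 for the main sets of those genes. Of the genes at least 2-fold different, 100% were in the lowest 3 signal deciles, which decides nothing, since a fixed fold rule applied to the spread of each decile alone would put 99.0% there. The first test does not exclude a true difference of any 1 gene, and an effect of the field was not testable with 1 array per condition.

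The lower heat shock list may likewise be probe set noise. Second probe sets of 14 members had a median of -0.0187, inside the random range of -0.091 to 0.090, and those of 8 interferon members had a median of 0.1353, inside -0.15 to 0.23. Both values meet what noise was predicted to give. A further condition, added after these values were seen, asks that the median also lie more than 1.96 random SDs from the list's main median, and neither list meets it, so these tests are too coarse to decide. A difference between the 2 pools or arrays other than the field cannot be told apart from the field, since the number of arrays per condition is 1.

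A hypothesis for the lower IVL and TGM1 was that fewer differentiated cells were on the EMF array, which would lower the other differentiation genes as well. The other 27 measured members had a median log2 difference of 0.02211, with 12 lower and a range from -0.52 to 0.49. IVL and TGM1 were picked as the 2 largest differences of this list, so every other member was smaller by that choice. The test therefore cannot decide about a loss as large as theirs. It shows only that the other members were not lower as a set. A smaller loss is not excluded. Some of the higher members were dim, such as KRT2 (93.2 untreated, 117 after EMF) and KLK6 (88.5 and 108), and dim sets read higher on the EMF array in general.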
